A study of Mus musculus with 32 samples.

How the data were processed

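Hearts of transgenic and control mice were profiled by poly(A) RNA-seq in 32 libraries, 4 for each of 8 groups of genotype, chamber and day. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded TruSeq mRNA kit. Per the submitters' processing notes, reads were trimmed with cutadapt, checked with FastQC, aligned with HISAT and quantified with StringTie on GRCm38 (mm10). Versions, the annotation release and the strand setting of the quantification are not given in the sources used here. The authors deposited FPKM values for 33612 genes and for 97393 transcripts, that is fragments normalized for transcript length and library depth, without counts. Each library had its own column, 0 library columns were left without a sample, and 0 pairs of libraries held identical values. Of 18184 genes with 1 transcript, 97.5% of values were equal in both tables within a relative tolerance of 0.001. FPKM is a relative unit: transcripts that take a large share of fragments, such as those of mitochondria, lower all others, and values of short genes, mitochondrial tRNAs and genes that share sequence with pseudogenes (Gapdh, ribosomal proteins) are uncertain. Since strand use is not stated, antisense and overlapping genes may share reads. Of the genes, 33501 were found in GENCODE M21, 99.5% with the same start and 91.5% with the same end. Coordinates are those of the deposited tables.

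Depth was estimated, since no counts were given. Among 10164 genes with a single exon and transcript, low values times length clustered in steps. The commonest step was taken as the worth of 1 fragment, which gave 16.1 to 19.6 M fragments per library, with a median of 18.9. A lower cluster, with 100 to 144 values per library against 125 to 191, was taken as that of single mates. Were it the worth of 1 fragment, the depth would be higher. At the depth used, the level of 3 fragments on 1 kb was 0.153 to 0.186 FPKM, a limit that covers counting error only. Genes with at least 1 FPKM numbered 9993 to 12257 per library, and the mean correlation of a library with its group mates was 0.954 to 0.991. An exact 0 can be a failed estimate, so genes at 0 in a whole group are described as listed at 0, with the values of each library.

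Groups were taken from sample titles, which give genotype, chamber, day and replicate. In 4 libraries, the control ventricles of day 0, a genotype field names the transgenic line, and the title was followed. Sex was taken from the same titles. The labels do not say whether libraries share animals. FPKM values were scaled by median ratios over 8726 genes (factors 0.852 to 1.32), and log2(scaled FPKM + 0.5) was fitted in limma 3.58.1 (R 4.3.3, with statmod 1.5.0 and data.table (1.17.8)). Genes needed at least 1 FPKM in at least 4 libraries of a fit. The fit of 24 ventricle libraries held 11235 genes and that of 16 day 0 libraries 12489, each with group and sex as terms, and with eBayes using trend and robust settings. Calls had a Benjamini-Hochberg adjusted p under 0.05, and those of at least 2-fold were counted separately. Contrasts compared days within genotype, genotypes within day, the change from day 0 to day 12 between genotypes, chambers, the genotype difference between chambers and, on day 12, between sexes. Isoforms were fitted likewise, and diffSplice tested whether isoforms of a gene changed unequally. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.

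Before the data were examined, the design, its alternatives, 30 pathway lists, 16 lists of cell type markers and the rule for named genes were fixed. That rule took Nr4a1, Nr4a2 and Nr4a3, up to 4 members of each list with the largest change among those that passed or the member of smallest p where none passed, and the 10 genes with the largest rise and fall among those that passed, reached 1 FPKM in the higher group and had libraries that did not overlap. Symbols of predicted genes (Gm and Rik names) were counted and not named, and some genes that the rule takes are not reported here. For isoforms it took the genes of a fixed list and the 5 of smallest p in the usage test. Wnk2, the single gene lower in transgenic ventricles on day 0, fell outside the rule and was chosen after its values were seen. List changes were tested with camera with a preset correlation of 0.01, with camera with an estimated correlation and with fry, adjusted over the lists of a comparison. Camera with the preset correlation called 138 of 546 list tests and with the estimated correlation 5.

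The steps were tested on simulated values with 200 genes changed. All groups otherwise had the same level, and noise was drawn independently for each gene or isoform. The real fit of day 12 called 5123 genes, so the shares recovered are not the sensitivity in the data themselves. For transgenic against control ventricles on day 12, limma recovered 60%, 84%, 96% and 98% of genes changed 1.25, 1.5, 2 and 4-fold. Between chambers it recovered 40%, 80%, 98% and 100%, for genotype in atria 22%, 72%, 88% and 100%, for the genotype difference between chambers 4%, 32%, 76% and 98%, and for the sex difference 4%, 22%, 84% and 96%. Isoform fits recovered 84% of 4-fold changes and the usage test 38%, with 15.4% of its calls false. Alternatives were pseudocounts of 0.1 and 1, no filter, a minimum of 5 FPKM, FPKM as deposited, quantile normalization, no sex covariate, the replicate label as a block, only the groups compared in the fit, limma's arrayWeights, camera with an estimated correlation, and each library left out in turn. A removal of each library's trend on transcript length (loess, span 0.5) and KEGG terms of the deposited gene table as gene groups (terms of 10 to 300 genes) were chosen after seeing the data. Fits were repeated for other splits of the libraries, all 35 where 4 met 4 and 100 drawn at random otherwise.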

Results

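The series followed the ventricular and atrial transcriptome of mice in which the nuclear receptor NR4A2 can be switched on in cardiomyocytes. NR4A2, also called Nurr1, is an orphan receptor that binds DNA and regulates transcription. The transgenic animals carried a conditional Nr4a2 cassette in the ROSA26 locus together with MerCreMer, a Cre recombinase fused to estrogen receptor domains and driven by the alpha-myosin heavy chain promoter, so that tamoxifen starts recombination in heart muscle cells. Littermates with MerCreMer alone served as controls for effects of Cre and tamoxifen. Tamoxifen was given once, at 40 mg/kg into the peritoneal cavity, to mice aged 8 to 9 weeks. Poly(A) RNA was sequenced in 32 libraries that form 8 groups of 4, each with 2 females and 2 males. Atria and ventricles of both genotypes were taken before tamoxifen (day 0), transgenic ventricles on days 3, 6 and 12, and control ventricles on day 12. No control group was given for days 3 and 6, so the comparisons of those days with day 0 hold tamoxifen and Cre effects as well as those of NR4A2. Levels are FPKM scaled between libraries, given as mean ± SD with n = 4 libraries per group, and changes are log2 fold changes ± standard error on the log2(scaled FPKM + 0.5) scale, which understates the change of low genes. The labels do not say whether the libraries of a group, or the atria and ventricles, came from separate animals, so p-values measure the spread between these samples. That spread and the standard errors were estimated over all groups of a fit, and need not match the spread within the groups compared. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over all genes tested. Depth was estimated from the commonest step among low values at 16.1 to 19.6 M fragments per library. At that depth 3 fragments on a transcript of 1 kb correspond to 0.153 to 0.186 FPKM. The 37 genes of the mitochondrial genome took 46.2% to 52.3% of the summed FPKM in ventricles and 30.2% to 41.6% in atria.

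Nr4a2 itself (ENSMUSG00000026826, GRCm38 chromosome 2, 57106830 to 57124003) separated the genotypes in every library. In ventricles it stood at 23.5 ± 4.20 FPKM in transgenic animals before tamoxifen, 47.0 ± 9.12 on day 3, 50.5 ± 4.31 on day 6 and 62.6 ± 8.92 on day 12. The control ventricles had 0.222 ± 0.0595 FPKM on day 0 and 0.228 ± 0.0230 on day 12. Transgenic atria had 14.6 ± 5.69 FPKM on day 0 and control atria 0.533 ± 0.113. Transcript ENSMUST00000028166 carried most of the Nr4a2 signal in transgenic ventricles, with 71.1 ± 10.2 FPKM on day 12, which is 99.96% ± 0.0506 of the summed transcripts of the gene. Transcript values were deposited separately from gene values, and this one exceeds its gene value, so the gene value is not the sum of its transcripts. For genes with 1 transcript, 97.5% of values were equal in both. Of the related receptors, Nr4a1 had 3.86 ± 2.39 FPKM in transgenic and 6.66 ± 1.39 in control ventricles on day 12 (log2 fold change -0.88 ± 0.41, adjusted p = 0.087, and -1.12 with 0.043 without transgenic male 1). Of the 2 family members tested on day 12, 1 rose and 0 fell over all genes (1 and 1 adjusted over the list alone). Nr4a3 was too low to be tested in ventricles, at 0.241 ± 0.115 and 0.470 ± 0.255 FPKM. The 4 day 0 control ventricles carry the transgenic genotype in 1 label field and are named controls in their titles. They were grouped by title, and their Nr4a2 values of 0.135 to 0.268 FPKM lie far below the 6.775 of the lowest transgenic library.

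**Figure D1:**
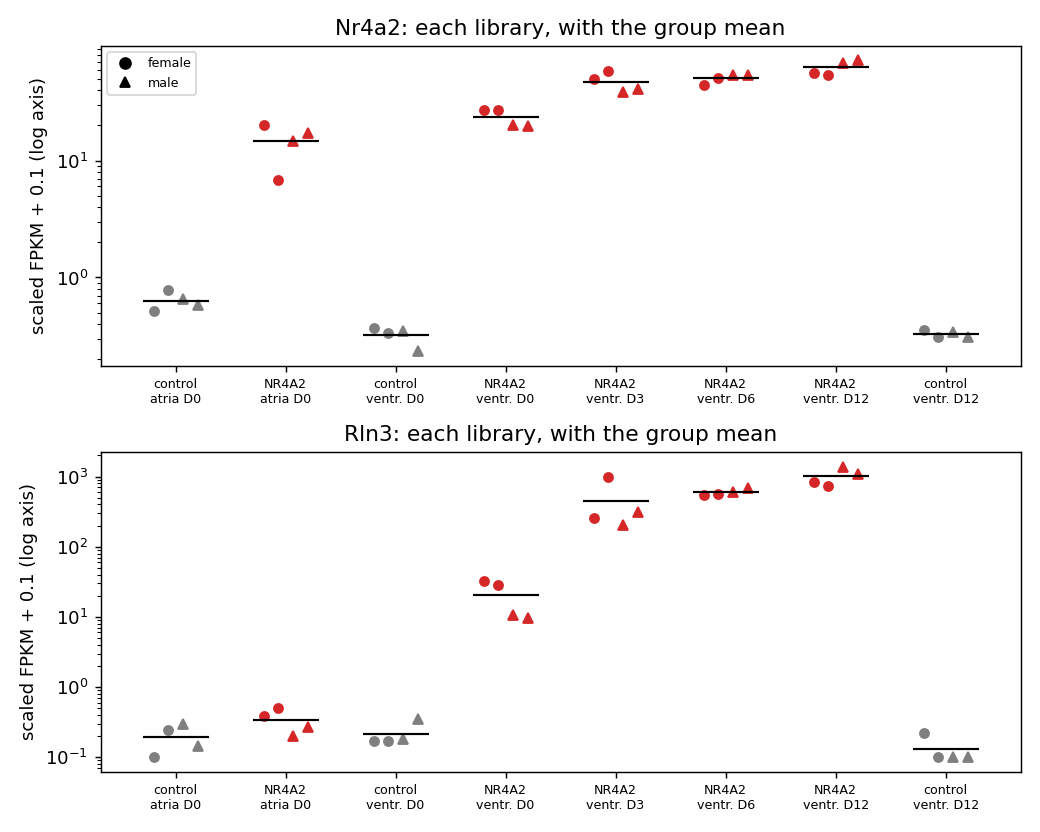
Scaled FPKM of Nr4a2 (top) and Rln3 (bottom) in each of the 32 libraries, on a log axis after adding 0.1. Columns are the 8 groups, circles females, triangles males, red transgenic, grey control, and lines group means. Nr4a2 in transgenic ventricles went from a mean of 23.5 before tamoxifen to 62.6 on day 12, and Rln3 from 20.3 to 1011.

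Before tamoxifen, the ventricles of the 2 genotypes differed in few genes. Of 11235 genes tested, 16 were higher and 1 was lower in transgenic ventricles. After Nr4a2 (log2 fold change 5.04 ± 0.12, adjusted p = 2.2e-17), the largest differences were in Rln3, the peptide hormone relaxin-3, at 20.3 ± 11.9 against 0.118 ± 0.0875 FPKM (4.88 ± 0.40), in Nptx1, neuronal pentraxin 1, at 1.41 ± 0.668 FPKM (1.86 ± 0.22), and in Gt(ROSA)26Sor, the non-coding transcript of the ROSA26 locus (chromosome 6, 113067428 to 113077333), at 8.07 ± 0.690 against 2.19 ± 0.627 FPKM (1.70 ± 0.26). Rln3 stood at 32.3 and 28.7 FPKM in the 2 transgenic females and at 10.5 and 9.55 in the 2 males. Nr4a2 had 27.1 and 27.2 against 20.0 and 19.8 FPKM, and a sex difference on day 0 was not tested. Grin2c, a glutamate receptor subunit, was higher by 1.10 ± 0.13 and Mov10l1 by 0.61 ± 0.06. Wnk2 was the gene that was lower, a call lost without control male 1 or 2 or transgenic female 1, female 2 or male 2 (adjusted p = 0.056 to 0.10). It was also lost with only these 2 groups in the fit (adjusted p = 0.36). Of the 16 higher genes, 15 were also higher on day 12 in libraries that share none with this comparison, where independent lists would share 3.69. Of the 2 genes tested in the NR4A family list, 1 was higher, also adjusted over the list alone, and this is Nr4a2 itself. No other member of the lists passed over all genes, and adjusted over the list alone 1 of 27 glycolysis genes, 1 of 16 cardiac stress genes and 2 of 7 atrial genes were higher. Eno3, the muscle enolase of glycolysis, had 841 ± 13.7 against 680 ± 61.9 FPKM (0.31 ± 0.07, adjusted p = 0.12) and the atrial natriuretic peptide gene Nppa 173 ± 12.8 against 95.5 ± 31.3 (0.90 ± 0.24, adjusted p = 0.31). The count was 9 with a pseudocount of 1 and 10 with only these 2 groups in the fit.

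On day 3 after tamoxifen, some genes of fuel use, conduction and calcium handling had changed in transgenic ventricles. Eno3 rose from 841 ± 13.7 to 4060 ± 284 FPKM (2.27 ± 0.07, adjusted p = 1.4e-15), and Pgam2, the muscle phosphoglycerate mutase, rose by 1.49 ± 0.09. Fabp3, which carries fatty acids in cardiomyocytes, fell from 1671 ± 121 to 607 ± 99.0 FPKM (-1.47 ± 0.12). Kcnip2, the subunit that sets the transient outward potassium current, fell from 45.4 ± 2.86 to 2.92 ± 0.798 FPKM (-3.77 ± 0.26), and Gja1, which encodes the main ventricular gap junction protein, fell by 1.60 ± 0.10 on the log2 scale. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 1.04 ± 0.09 and Slc8a1, the sodium-calcium exchanger, rose by 1.07 ± 0.09. Rln3 rose to 443 ± 371 FPKM (4.32 ± 0.40), with 995 in female 2 and 207 to 316 in the other 3 (3.84 without female 2), Nptx1 by 3.27 ± 0.22, Slc45a3 by 3.05 ± 0.13, the interferon regulatory factor Irf5 by 2.92 ± 0.11 and Fhl1, a LIM protein of stressed myocardium, by 2.27 ± 0.21 (1.99 without female 2), while Lrrc2 changed by -2.14 ± 0.13. In all, 1959 genes rose and 1749 fell between day 0 and day 3, 184 and 130 of them at least 2-fold. With FPKM as deposited, 1497 rose and 2311 fell.

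Of the 27 glycolysis genes tested, 18 rose and 5 fell on day 3 (19 and 6 adjusted over the list alone). Of 34 fatty acid uptake and oxidation genes, 3 rose and 13 fell (the same counts adjusted over the list alone). Of 25 ion channel and conduction genes, 7 rose and 14 fell (8 and 16 adjusted over the list alone), of 12 ventricular genes 1 rose and 6 fell (1 and 9 adjusted over the list alone), and of 12 endothelial markers 11 fell, also adjusted over the list alone. Camera with its preset correlation called these 5 lists, and with an estimated correlation their adjusted p-values were 0.13, 0.91, 0.64, 0.13 and 0.39. It did not call calcium handling, where 2 of 19 rose and 9 fell (3 and 10 adjusted over the list alone). Nuclear encoded respiratory chain genes had 14 of 52 up and 4 down (15 and 4 adjusted over the list alone), among them Sdhd at 0.50 ± 0.05, but with quantile normalization 11 rose and 12 fell. The tricarboxylic acid cycle had 7 of 22 up and 1 down, and 4 up and 4 down with quantile normalization. In the extracellular matrix list 1 of 33 rose and 1 fell, and 0 did when adjusted over the list alone. Among circadian clock genes 3 of 17 rose and 1 fell.

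Between day 3 and day 6 few genes passed in limma, 272 of 11235, though 1757 had an unadjusted p under 0.05. In 10.2% of genes the libraries of the 2 days did not overlap, where chance gives 2.86%. Nr4a2 was 0.12 ± 0.12 above its day 3 level (adjusted p = 0.70), Eno3 stood at 4206 ± 79.3 FPKM and Kcnip2 at 3.13 ± 1.43. Against day 0, 2074 genes rose and 2028 fell (1378 and 3252 with FPKM as deposited, which moved the median of all genes by -0.107). Against day 3, 157 rose and 115 fell (88 and 234 with FPKM as deposited). That count was 126 with only the 2 groups in the fit and 672 with library weights, and it was between 108 and 160 when any of 5 libraries was left out, namely males 1 and 2 of day 3 and female 2 and males 1 and 2 of day 6. Of 34 fatty acid genes, 10 fell from day 3 to day 6 and 0 rose (18 and 0 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation), among them Slc25a20, the mitochondrial carnitine carrier, by -0.61 ± 0.10. Ptgds, a prostaglandin synthase, changed by -1.48 ± 0.26, whereas Pam, an enzyme that amidates peptides, rose by 0.52 ± 0.05 and Lnp1 by 1.18 ± 0.08. Of 17 interferon response genes 1 rose (10 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation), and 0 did with FPKM as deposited or with quantile normalization.

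Between day 0 and day 6, 19 of 27 glycolysis genes rose and 5 fell (20 and 5 adjusted over the list alone, adjusted p = 0.25 with an estimated correlation). Of 34 fatty acid genes, 1 rose and 23 fell (1 and 26 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation). Pdk4, which encodes a kinase that inhibits pyruvate dehydrogenase, changed by -2.84 ± 0.31, from 118 ± 36.5 to 15.3 ± 1.32 FPKM. Respiratory chain genes still showed 16 up and 4 down of 52, but 9 and 9 with FPKM as deposited and 15 and 9 with quantile normalization. Of the 13 mitochondrially encoded genes, 9 rose (12 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), and 0 with quantile normalization. In the tricarboxylic acid cycle list 10 of 22 rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.89 with an estimated correlation). Endothelial markers again showed 11 of 12 lower (adjusted p = 0.25 with an estimated correlation). In the matrix list 4 of 33 rose and 2 fell, but 2 rose and 3 fell with FPKM as deposited. Of 17 clock genes 10 rose and 4 fell (the same adjusted over the list alone), the fallers including Npas2 at -1.16 ± 0.19. Since hours of collection are not given, in comparisons with day 6 the hour cannot be told apart from the day.

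From day 6 to day 12 most respiratory chain genes fell, and some matrix genes rose. Of 52 respiratory chain genes, 50 fell and 0 rose (51 and 0 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation). Cyc1, the cytochrome c1 subunit of complex III, changed by -0.56 ± 0.07, from 367 ± 7.36 to 248 ± 5.83 FPKM, Cox5b by -0.56 ± 0.09 and Uqcrc1 by -0.55 ± 0.08. With FPKM as deposited 44 fell, and with quantile normalization 33. In the tricarboxylic acid cycle 12 of 22 fell (18 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation), among them Sdhb at -0.52 ± 0.08. Fatty acid genes had 16 of 34 lower and 0 higher (19 and 2 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), with Acaa2, a thiolase of beta-oxidation, at -0.62 ± 0.10. Of the mitochondrially encoded genes 9 of 13 fell (11 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), with mt-Nd1 at -0.34 ± 0.07, but 0 with quantile normalization. Glycolysis had 3 of 27 up and 8 down (4 and 11 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), with Eno3 at -0.40 ± 0.07, but 6 up and 5 down with FPKM as deposited and 3 up and 2 down with quantile normalization. Eno3 itself changed by -0.16 with quantile normalization and did not pass (adjusted p = 0.12).

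In the same interval 7 of 33 matrix genes rose and 0 fell (12 and 1 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), and 2 of 12 fibroblast markers rose and 0 fell (4 and 0 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), Mfap5 by 0.61 ± 0.17 and Dcn by 0.27 ± 0.09. Thbs1, the matricellular protein thrombospondin 1, rose by 1.03 ± 0.24, and Ccn2, a matricellular growth factor, from 19.9 ± 3.35 to 51.8 ± 6.92 FPKM (1.36 ± 0.25). Cdkn1a, the cell cycle inhibitor p21, rose by 1.11 ± 0.24 (adjusted p = 0.056 without the sex covariate), from 2.37 ± 0.0392 to 5.91 ± 1.88 FPKM, with 5.14 ± 2.95 on day 3 and 7.96 ± 1.95 in control ventricles of day 12. The imprinted non-coding RNAs Meg3 and Rian rose by 2.03 ± 0.15 and 1.96 ± 0.12. Among clock genes Arntl was up by 1.61 ± 0.32 and Npas2 up by 1.36 ± 0.19, with Dbp at -1.66 ± 0.43 (adjusted p = 0.057 and 0.052 without female 1 or female 2 of day 6) and Ciart at -2.11 ± 0.48. Of the 17 clock genes 4 rose and 9 fell (4 and 10 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation). The labels do not give the hour of collection. Of all genes, 574 rose and 781 fell between days 6 and 12. FPKM as deposited gave 2207 and 375 (median of all genes 0.123), library weights gave 2488 calls, and leaving out female 1 of day 6, or female 1 or male 2 of day 12, gave 803, 899 or 900. Nr4a2 was 0.30 ± 0.12 higher (adjusted p = 0.12).

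**Figure D2:**
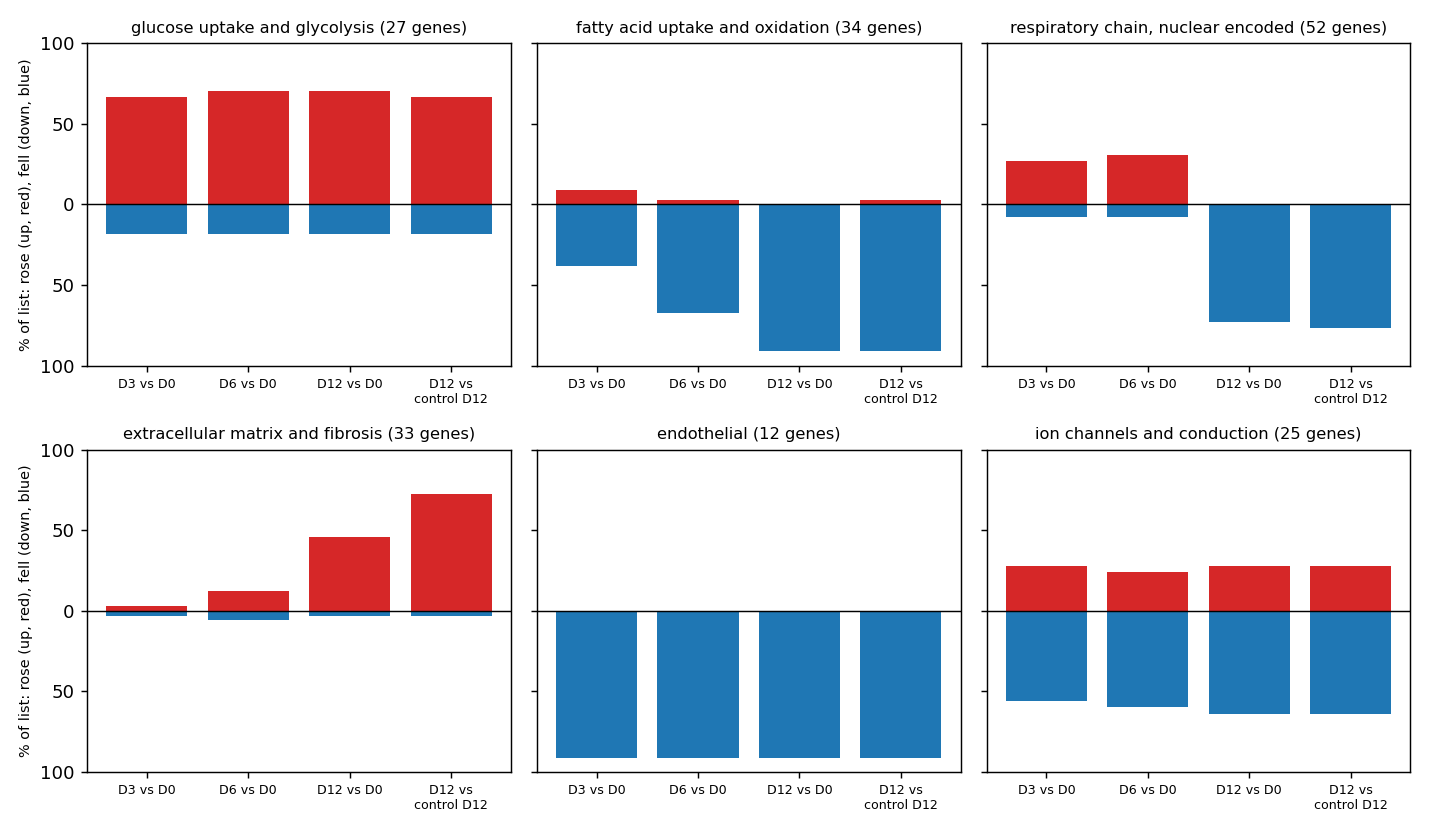
Share of each gene list that rose (red, upward) or fell (blue, downward) at adjusted p under 0.05, in percent of the genes tested, in transgenic ventricles on days 3, 6 and 12 against day 0 and on day 12 against control ventricles of day 12. Respiratory chain genes rose in 16 of 52 cases by day 6 (9 up and 9 down with FPKM as deposited) and fell in 38 by day 12, while fatty acid genes fell in 13, 23 and 31 of 34 cases.

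The comparison with controls of the same day asked what differed when both genotypes had received tamoxifen and carried Cre. On day 12, transgenic ventricles had 2588 genes higher and 2535 lower than control ventricles, of 11235 tested, 379 and 203 of them at least 2-fold. Together the calls were 45.6% of the genes tested, a share to set beside the list counts of this comparison. In 39.9% of genes the libraries of the 2 groups did not overlap, where chance gives 2.86%. After Rln3 (1011 ± 289 FPKM against 0.122 in 1 control library and 0 in the other 3) and Nr4a2 (6.43 ± 0.12, adjusted p = 7.3e-20), Nptx1 (28.8 ± 1.99 FPKM), the cytokine gene Clcf1 (14.5 ± 0.677 against 0.364 ± 0.145 FPKM), Lypd6b (8.40 ± 1.34 FPKM) and the carbonic anhydrase gene Car9 (4.19 ± 0.46) were among the 10 with the largest rise. Car9 had 42.7 FPKM in transgenic male 1 and 5.06 to 6.87 in the other 3. Ephx4, Lnp1, Myh8 and Nps were listed at 0 in all 4 control libraries. In the 2 female and then the 2 male transgenic libraries the levels were 10.2, 8.63, 14.3 and 11.3 FPKM for Ephx4, 8.78, 7.89, 11.2 and 9.52 for Lnp1, 7.32, 7.29, 11.0 and 7.83 for Myh8, a perinatal myosin heavy chain, and 5.28, 4.20, 23.3 and 8.47 for Nps. Among the largest falls were Kcnip2 (4.02 ± 2.06 against 50.8 ± 2.08 FPKM), Acta1, the skeletal alpha-actin (15.8 ± 14.0 against 112 ± 37.9, with 20.8, 5.58, 33.3 and 3.57 in the 4 transgenic libraries), Lrrc15 (-2.66 ± 0.18) and Wfdc1 (-2.54 ± 0.12).

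Most fatty acid oxidation genes were lower and most glycolysis genes higher on day 12. Of 34 fatty acid uptake and oxidation genes, 31 fell and 1 rose (the same adjusted over the list alone, median -0.83). Fabp3 stood at 446 ± 73.3 against 1769 ± 218 FPKM (-1.99 ± 0.12), Dgat2, which makes triglyceride, changed by -1.84 ± 0.10, the lipid droplet gene Plin5 by -1.68 ± 0.12 and Pdk4 by -1.66 ± 0.31. Of 27 glycolysis genes, 18 rose and 5 fell (the same adjusted over the list alone, median 0.61). Eno3 reached 3194 ± 204 against 709 ± 75.2 FPKM (2.17 ± 0.07), the lactate exporter gene Slc16a3 7.70 ± 1.02 against 0.303 ± 0.0654 (3.35 ± 0.20), Pkm rose by 1.40 ± 0.07 and Pfkm, the muscle phosphofructokinase, by 1.38 ± 0.06. In the ketone and branched chain amino acid list 12 of 19 fell and 1 rose (13 and 1 adjusted over the list alone), with Bckdhb at -0.88 ± 0.07. Camera with its preset correlation called these 3 lists, and with an estimated correlation their adjusted p-values were 0.37, 0.37 and 0.41.

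Respiratory chain genes fell in 40 of 52 cases and rose in 0 (41 and 0 adjusted over the list alone, median -0.36, adjusted p = 0.50 with an estimated correlation). Cox8b stood at 174 ± 5.43 against 354 ± 68.9 FPKM (adjusted p = 3.1e-08), Cox6a2 changed by -0.90 ± 0.09 and the adenine nucleotide carrier gene Slc25a4 by -0.78 ± 0.08. Control female 1 of day 12 held more RNA of short transcripts than its group mates: across genes, the rank correlation of its deviation from the mean of its group mates with transcript length was -0.55, against 0.25 to 0.39 in the other 3 controls and -0.21 to 0.23 in the other ventricle groups. Without that library 40 of the 52 genes still fell and 1 rose, with a median of -0.29. Of 22 tricarboxylic acid cycle genes, 12 fell and 2 rose (the same adjusted over the list alone, adjusted p = 0.77 with an estimated correlation), with Idh2 at -1.09 ± 0.07 and Dlat, a pyruvate dehydrogenase subunit, at 1.02 ± 0.05. The 13 mitochondrially encoded genes had 5 higher and 0 lower, with mt-Nd5 at 0.28 ± 0.07, but 2 higher and 3 lower with quantile normalization. Among metabolic transcription regulators 4 of 25 rose and 8 fell, the risers including Tbx20 (1.70 ± 0.09) and the coactivator gene Ppargc1b (1.59 ± 0.13).

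Conduction, calcium and contractile genes moved in both directions. Of 25 ion channel and conduction genes 16 fell and 7 rose (the same adjusted over the list alone, adjusted p = 0.41 with an estimated correlation). Kcnip2 (-3.62 ± 0.26), the sodium channel subunit gene Scn4b (-1.97 ± 0.18), the pacemaker channel gene Hcn2 (-1.52 ± 0.17) and Gja1 (13.2 ± 2.38 against 37.5 ± 5.03 FPKM) were lower. In the calcium handling list 8 of 19 fell and 3 rose (9 and 3 adjusted over the list alone), with Atp2a2 at 640 ± 99.0 against 1706 ± 127 FPKM (-1.42 ± 0.09), the calcium release channel gene Ryr2 at -0.84 ± 0.13 and Slc8a1 at 1.16 ± 0.09. Adult sarcomere genes had 10 of 21 lower and 7 higher (11 and 7 adjusted over the list alone), with the myosin light chain gene Myl3 at -1.50 ± 0.11, Tnnc1 at -1.02 ± 0.10 and Smyd1, a methyltransferase of sarcomere assembly, at 1.26 ± 0.05. Cardiac stress and fetal genes had 6 of 16 up and 3 down (6 and 5 adjusted over the list alone), and 5 of each with FPKM as deposited. Fhl1 rose from 25.3 ± 0.717 to 292 ± 103 FPKM and Uchl1 by 2.06 ± 0.15, while Acta1 fell. The list of atrial genes had 3 of 7 up and 3 down (4 and 3 adjusted over the list alone), with Pam at 1.65 ± 0.05 and the potassium channel gene Kcnj3 at -0.82 ± 0.14, and that of ventricular genes 3 of 12 up and 5 down (3 and 7 adjusted over the list alone). Control female 1 stood apart from the other 3 controls in Myl3, Tnnc1, Ryr2 and Kcnj3, and without it these changed by -1.36, -0.89, -0.97 and -0.92. Camera called none of these lists but that of the ion channels.

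**Figure D3:**
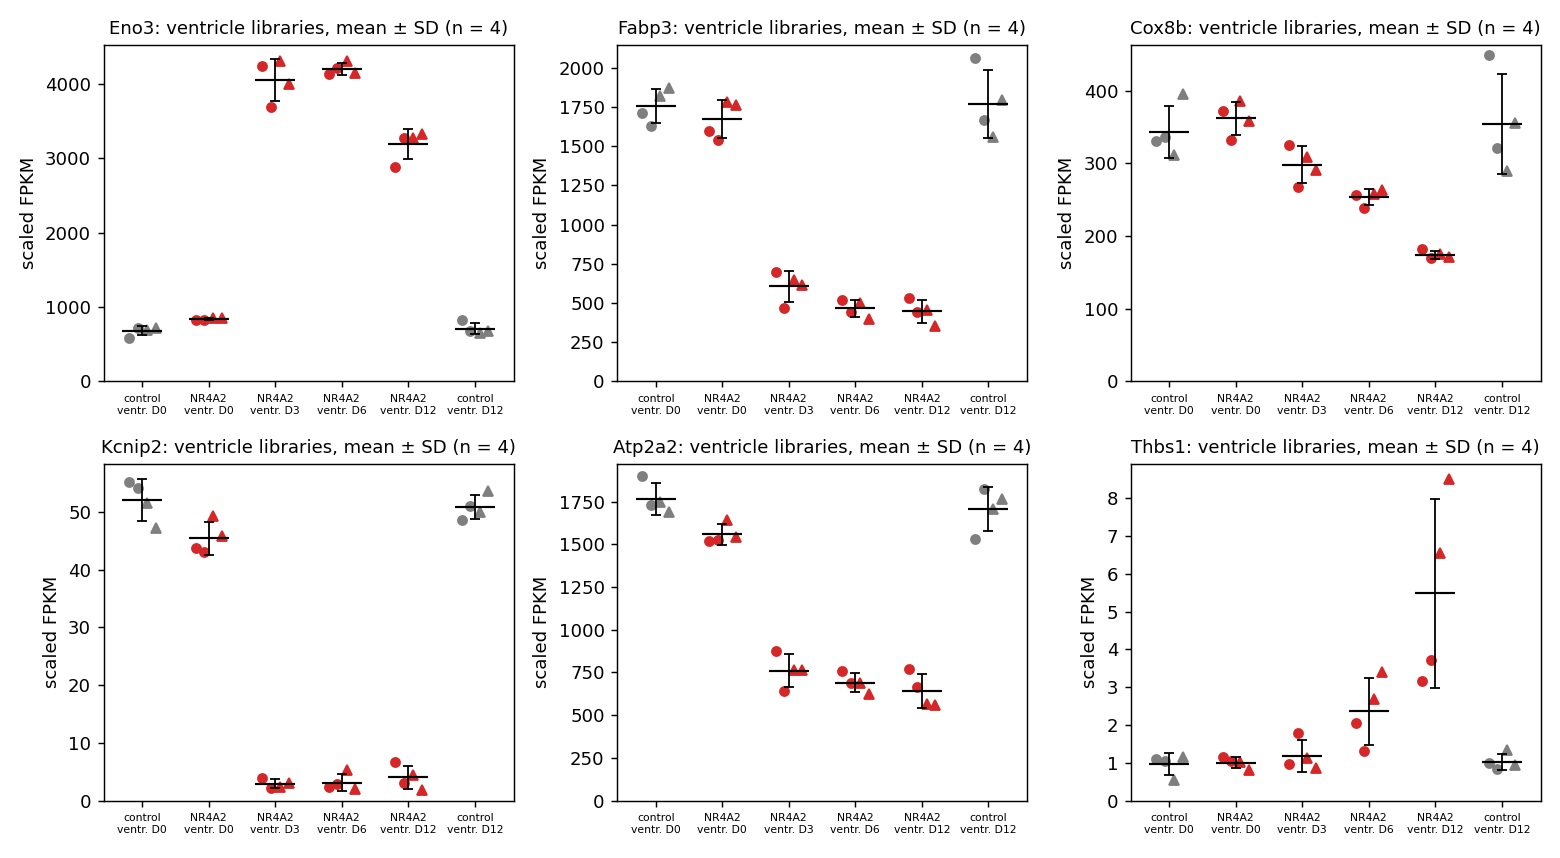
Scaled FPKM of 6 genes in the 24 ventricle libraries (circles females, triangles males), with group mean and SD, n = 4. Eno3, Fabp3, Kcnip2 and Atp2a2 had changed by day 3, with Eno3 at a mean of 4060, whereas Cox8b reached its mean of 174 and Thbs1 its mean of 5.49 on day 12. Red points are transgenic and grey points control libraries.

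Most matrix genes were higher and most endothelial markers lower on day 12. Of 33 extracellular matrix genes 24 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), with Thbs1 at 5.49 ± 2.50 against 1.03 ± 0.209 FPKM (1.88 ± 0.24), Col8a1 at 1.83 ± 0.18 and the fibroblast activation gene Postn at 1.37 ± 0.28. Fibroblast markers had 7 of 12 up and 0 down (the same adjusted over the list alone, adjusted p = 0.77 with an estimated correlation), with Col1a1 at 0.70 ± 0.19. Without transgenic male 1, which stood apart in both, Col8a1 changed by 1.65 and Col1a1 by 0.55. Of 12 endothelial markers 11 fell (the same adjusted over the list alone, adjusted p = 0.37 with an estimated correlation), with Fabp4 at -0.82 ± 0.09 and Tie1 at -0.55 ± 0.07. Cardiomyocyte markers had 2 of 10 up and 4 down (2 and 6 adjusted over the list alone), mural cell markers 2 of 9 up and 5 down, with the pericyte gene Rgs5 at -0.50 ± 0.06, endocardial markers 1 of 4 up, Npr3 at 1.62 ± 0.10, and 1 down, and macrophage markers 0 of 13 up and 3 down (1 adjusted over the list alone), with C1qa at -0.44 ± 0.18 (adjusted p = 0.069 to 0.13 without transgenic female 1, female 2 or male 2, or control female 1 or male 1). The markers of rarer cell types that could be tested were few. The T and NK cell marker Trac rose by 1.24 ± 0.18, the 1 B cell marker, Ighm, changed by -0.62 ± 0.19, 1 of 6 erythroid and blood markers, Pf4, by -0.55 ± 0.19 and 1 of 2 Schwann and neuron markers, Dbh, by -0.94 ± 0.13. Of 2 adipocyte markers Cidea rose by 1.12 ± 0.14 and the other, Fabp4, is also in the endothelial list. The 1 monocyte and neutrophil marker (Ly6c2, adjusted p = 0.20), 2 mesothelial markers (Msln, adjusted p = 0.18) and 2 thymus and lymph node markers (Cd1d1, adjusted p = 0.12) did not pass, and 0 lung markers were tested. Both skeletal muscle markers tested fell (adjusted p = 0.37 with an estimated correlation), Acta1 and Ckm, which heart muscle also expresses and which changed by -2.27 ± 0.15.

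Among stress and signalling lists, 17 of 21 unfolded protein response genes fell and 2 rose (the same adjusted over the list alone, adjusted p = 0.37 with an estimated correlation), with the chaperone gene Hspa5 at 56.3 ± 7.41 against 113 ± 11.1 FPKM. Of 27 oxidative stress genes 12 fell and 4 rose (14 and 5 adjusted over the list alone, adjusted p = 0.50 with an estimated correlation), with the glutathione transferase gene Gstm1 at -0.83 ± 0.08. Growth signalling had 13 of 29 up and 3 down (the same adjusted over the list alone, adjusted p = 0.41 with an estimated correlation), with the phosphatase gene Dusp5 at 1.68 ± 0.23 and Ccn1 at 1.58 ± 0.14. Serine, one carbon and ATF4 target genes had 6 of 18 up and 1 down, with Aldh18a1 at 1.21 ± 0.11. Hypoxia and angiogenesis genes had 6 of 19 up, among them Hif1a at 1.24 ± 0.13, and 7 down, among them Apln at -1.63 ± 0.12, and 6 of each with quantile normalization. Cytokine and inflammation genes had 4 of 21 up, among them osteopontin, Spp1, at 2.22 ± 0.25, and 4 down (4 and 0 adjusted over the list alone). Of 17 p53 target genes 6 rose, with Phlda3 at 0.95 ± 0.14, and 4 fell, with Sesn1 at -0.90 ± 0.09, and 4 of each did with FPKM as deposited. Apoptosis genes had 5 of 18 up, with Bnip3l at 0.69 ± 0.06, and 6 down. Autophagy and proteolysis genes had 4 of 25 up and 8 down (5 and 8 adjusted over the list alone), with the ubiquitin ligase gene Fbxo32 at -0.99 ± 0.11, but 6 of each with quantile normalization. In the cell cycle list 4 of 12 fell and 0 rose, with Ccnd2 at -0.67 ± 0.09. Of 17 interferon response genes 1 rose, and with quantile normalization 1 rose and 2 fell. Immediate early genes had 3 of 15 up, with Egr1 at 1.69 ± 0.50 (adjusted p = 0.067 with only the groups compared in the fit), and 1 down. Of the 6 NR4A2 target genes of dopamine neurons tested, 4 fell, with the dopamine receptor gene Drd2 at -0.99 ± 0.19, and 1 rose (5 and 1 adjusted over the list alone). Of 17 clock genes 2 rose, Dbp at 1.10 ± 0.43 (adjusted p = 0.046, and 0.065 to 0.17 without any 1 library but control female 2) and Bhlhe41 at 0.61 ± 0.19, and Hlf fell by 0.62 ± 0.19 on the log2 scale, but 1 rose and 2 fell with FPKM as deposited, without the sex covariate or without control female 1, and 2 of each with quantile normalization. The 4 sex chromosome genes did not pass (Ddx3y, adjusted p = 0.24). Over all 11235 genes tested, 45.6% passed on day 12, 2588 up and 2535 down. A list with a similar share passing therefore does not stand out. Counts adjusted over the list alone were the same as over all genes where none is given.

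Control ventricles did not change detectably between day 0 and day 12. None of 11235 genes passed in limma, 894 had an unadjusted p under 0.05, and the smallest adjusted p was 0.11. Of other fits, 2 genes passed with FPKM as deposited, 1 with quantile normalization, 7 with library weights, and 8, 4, 4 and 1 without female 2, male 1 or male 2 of day 0 or female 2 of day 12. Of 17 clock genes 5 were lower when adjusted over the list alone (adjusted p = 0.81 with an estimated correlation). Against day 0 of their own genotype, transgenic ventricles of day 12 had 2369 genes higher and 2457 lower, 31 of 34 fatty acid genes lower, 38 of 52 respiratory chain genes lower, 19 of 27 glycolysis genes higher and 15 of 33 matrix genes higher (31, 40, 19 and 16 adjusted over the list alone, adjusted p = 0.31, 0.59, 0.29 and 0.81 with an estimated correlation). Kcnip2 changed by -3.46 ± 0.26, Fabp3 by -1.92 ± 0.12 and Ptgds by -2.94 ± 0.26. The test of whether this change differed from that in controls called 1808 genes with the higher and 1700 with the lower change in transgenic ventricles. Rln3 (5.98 ± 0.57), Eno3 (1.86 ± 0.10), Thbs1 (1.82 ± 0.35) and Nr4a2 (1.38 ± 0.18) changed more in the transgenic direction, and Kcnip2 (-3.42 ± 0.36), Fabp3 (-1.92 ± 0.18), Cox8b (-1.08 ± 0.14) and Gt(ROSA)26Sor (-2.38 ± 0.36) had the lower change. The lists gave 28 of 34 fatty acid genes, 37 of 52 respiratory chain genes, 14 of 25 ion channel genes and 10 of 12 endothelial markers with the lower change, and 16 of 27 glycolysis genes and 13 of 33 matrix genes with the higher (31, 40, 15, 10, 17 and 15 adjusted over the list alone, adjusted p = 0.30, 0.52, 0.37, 0.30, 0.30 and 0.76 with an estimated correlation). Of the genes that rose from day 0 to day 3, 1395 of 1959 were also higher than controls on day 12, and 1194 of 1749 that fell were lower, in libraries that share none. Independent lists would share 451 and 395.

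Isoform values gave unequal change within genes on day 12. Of 19754 isoforms fitted, 2102 were higher and 2071 lower in transgenic than in control ventricles, from 3633 genes, and 106 of the higher and 113 of the lower belonged to genes that did not pass or were not tested at the gene level. The diffSplice F test called 172 of 4461 genes. In Pfkm, ENSMUST00000230445 (GRCm38 chromosome 15, 98092644 to 98132451) reached 472 ± 55.2 against 23.3 ± 3.39 FPKM, from 7.37% ± 0.789 to 56.8% ± 6.33 of the gene, whereas ENSMUST00000051226, which starts at 98108466, had 360 ± 61.1 against 292 ± 9.84. Both have 23 exons. In Ano10, a gene of the TMEM16 family, the 2-exon transcript ENSMUST00000216738 fell from 37.9 ± 7.05 to 1.64 ± 0.605 FPKM and from 83.8% ± 4.04 to 21.4% ± 5.86 of the gene, and the 13-exon ENSMUST00000042546 had 5.74 ± 0.236 against 6.77 ± 1.27 FPKM. In Grb14, an adaptor of insulin signalling whose gene-level change was 0.02 (adjusted p = 0.84), ENSMUST00000156765 rose from 1.59 ± 0.498 to 7.71 ± 0.885 FPKM. In Pkm, ENSMUST00000215660 rose from 0.148 ± 0.117 to 6.95 ± 1.08 FPKM, which is 0.535% ± 0.0526 of the gene, and in Meg3 ENSMUST00000143836 rose from 0.958 ± 0.273 to 48.5 ± 19.7 FPKM. On simulated data the usage test recovered 38% of the isoforms changed 4-fold, and 15.4% of its calls were false, so single calls are uncertain. With a minimum of 5 FPKM it called 85 genes, and without a filter 2447.

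Sex was tested as a difference in the genotype effect on day 12, with 2 libraries per sex and genotype. The smaller groups limited this test, which recovered 22% of simulated differences of 1.5-fold and 84% of those of 2-fold. One gene passed, Ackr3, a scavenger receptor for chemokines, whose effect was lower in males by -1.04 ± 0.13 (adjusted p = 0.0056), and 955 genes had an unadjusted p under 0.05. Nr4a2 differed by 0.36 ± 0.12 (adjusted p = 0.54). Each library decided this count: without transgenic female 1, female 2, male 1 or male 2 it was 0, 2, 3 or 6, and without control female 1, female 2, male 1 or male 2 it was 2, 226, 0 or 3. A lone library of a sex is then assumed to vary like the others. Without a filter 14 genes passed, and with only the 2 groups in the fit 3.

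Atria and ventricles of day 0 differed in most genes. Of 12489 genes tested over both genotypes, 4954 were higher in atria and 3373 higher in ventricles, 1002 and 600 at least 2-fold. FPKM as deposited gave 8727 and 1503 (median of all genes 0.439) and quantile normalization 3625 and 4383 (median -0.039), so the balance of directions depends on the scaling. Of 16 atrial genes 15 were higher in atria and 1 lower (adjusted p = 0.0039 with an estimated correlation), with the atrial light chain gene Myl7 at 12.73 ± 0.21, sarcolipin, Sln, at 11.04 ± 0.09, Nppa at 6.94 ± 0.17, Bmp10 at 8.56 ± 0.15, the connexin gene Gja5 at 4.11 ± 0.09 and Kcnj3 at 3.18 ± 0.11. All 12 ventricular genes were lower in atria (adjusted p = 0.035 with an estimated correlation), with the ventricular light chain gene Myl2 at -8.10 ± 0.59 and the transcription factor gene Irx4 at -4.54 ± 0.07. Esr1, which shares estrogen receptor sequence with MerCreMer, had 183 ± 43.0 FPKM in control ventricles and 5.61 ± 2.08 in control atria (-4.99 ± 0.15 over both genotypes), and whether these reads come from the gene or from MerCreMer was not tested.

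Most energy metabolism genes were lower in atria, and fibroblast and mesothelial markers higher. Lower were 30 of 34 fatty acid genes, with Plin5 at -2.43 ± 0.13, 45 of 52 respiratory chain genes, with Uqcrc1 at -1.59 ± 0.08, 22 of 22 tricarboxylic acid cycle genes, 13 of 13 mitochondrially encoded genes, 17 of 19 ketone and branched chain amino acid genes, with Oxct1 at -1.69 ± 0.06, 18 of 21 sarcomere genes and 8 of 9 mural markers. In these lists 0 genes were higher, but for 1 of the sarcomere. Their adjusted p-values with an estimated correlation were 0.092, 0.35, 0.067, 0.10, 0.026, 0.087 and 0.026. All 12 fibroblast markers, decorin (Dcn) among them, and all 8 mesothelial and epicardial markers, with Upk3b at 5.94 ± 0.29 and Msln at 5.17 ± 0.29, were higher in atria (adjusted p = 0.19 and 0.15 with an estimated correlation). Adjusted over the list alone, 31 fatty acid and 46 respiratory chain genes were lower, and the other counts were the same.

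In atria before tamoxifen, 3 of 12489 genes differed between the genotypes, and 1596 had an unadjusted p under 0.05. Nr4a2 was higher in transgenic atria by 3.78 ± 0.24 (adjusted p = 2.2e-06) and Gt(ROSA)26Sor by 0.92 ± 0.13 (6.31 ± 0.594 against 3.08 ± 0.154 FPKM), and Ptpn14 was lower by -0.50 ± 0.07. Transgenic female 2 had the lowest agreement, with a mean correlation of 0.954 to its group mates against 0.976 to 0.978 for the others, and without it 6 genes passed. Without control female 2, 5 passed, with Ptpn14 lost (adjusted p = 0.071). Without control female 1, male 1 or male 2, or transgenic male 2, 1 passed, with adjusted p = 0.088 to 0.13 for Gt(ROSA)26Sor and 0.10 to 0.24 for Ptpn14. With the replicate block these 2 genes did not pass either (adjusted p = 0.084 and 0.098). Ptpn14 was also lost without a filter (0.052), with FPKM as deposited (0.064) and with only the groups compared in the fit (0.38). Library weights gave 45 genes, a pseudocount of 1 gave 15, no filter 6, and quantile normalization gave 3 higher and 10 lower. The genotype difference was larger in ventricles than in atria for 1 gene, Rln3, which had 0.239 ± 0.131 FPKM in transgenic and 0.0964 ± 0.0910 in control atria (difference of log2 fold changes -4.57 ± 0.40, adjusted p = 1.6e-04). That count was 2 without male 1 or male 2 of the control ventricles, and 4 without a filter or with library weights. For Nr4a2 the difference was -1.27 ± 0.34 (adjusted p = 0.92), and 589 genes had an unadjusted p under 0.05. Transgenic atrial female 2 lowers the atrial mean of Nr4a2, at 6.775 FPKM against 20.11, 14.55 and 16.94 in female 1, male 1 and male 2.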

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

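Tests of other splits of the libraries, of the Nr4a2 level before tamoxifen, of the atrial library, of the hour of collection, of the scaling and of the transcript length trend were chosen only after the result was seen, though for respiratory chain and ribosome genes the bounds of the length trend tests were written before their values were.

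Respiratory chain genes fell in 50 of 52 cases from day 6 to day 12 and in 40 of 52 against controls of day 12, and ribosome genes fell in 101 of 130 against controls. The trend on transcript length is argued against as the whole cause: with it removed, 46 of 52 still fell between days 6 and 12 (median -0.30 from -0.41) and 74 of 130 ribosome genes against controls (median -0.19 from -0.29), and without control female 1, the library with the strongest trend, 40 of 52 respiratory chain genes and 71 of 130 ribosome genes (median -0.20) fell against controls. Scaling is argued against as the whole cause of the fall from day 6 to day 12, since 33 of 52 fell in the lower of the other scalings. That count is below the 50 of the main fit, so scaling may add to the fall. This test did not cover the fall against controls. The smaller medians without the trend leave open that it may add to the fall, and for the fall from day 6 to day 12 the hour of collection cannot be told apart from the days, since 13 of 17 clock genes changed and hours are not given, whereas 3 of 17 changed against controls of day 12. A biological difference between the genotypes stays open, and camera with an estimated correlation did not call the list.

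Nr4a2 RNA stood at 37.3% of its day 12 excess before tamoxifen. A fraction of cells already induced, or induced tissue mixed in, is argued against as the whole of this level. The 378 genes at least doubled on day 12 had a median of 4.28% of their excess on day 0 (quartiles 1.36% and 7.63%). Rln3 had 1.99%, Nptx1 4.89%, Ephx4 4.43%, Lnp1 4.41%, Myh8 3.92%, Meg3 5.37% and Rian 5.58%. A small induced fraction, of the size of these shares, stays open. Libraries of later days labelled as day 0 are argued against in ventricles: the highest median of these genes in a single library of day 0 was 5.48%, and the lowest on days 3 and 6 was 54.2%. Transcription from the allele before recombination may account for it: the neighbouring Gt(ROSA)26Sor was higher in transgenic libraries on day 0 and changed by -1.77 (log2) by day 3. This remains a hypothesis, since reads over the allele were not examined and Rln3 was also higher before tamoxifen.

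Female 2 of the transgenic atria had a mean correlation of 0.954 with its group mates, with Nppa at 33220, Myl7 at 11520 and Msln at 54.1 FPKM, each far from the other 3, and 30.2% of summed FPKM in mitochondrially encoded genes, against 38.0% to 41.6% in the other 7 atrial libraries. Ventricular tissue is argued against by Myl2 at 4.85 FPKM, within the 0.893 to 58.4 of the other 7 atrial libraries. Short transcripts were over-represented, with a rank correlation of its deviation with length of -0.61 against 0.047 to 0.48 in the others, but they are argued against as the whole difference: 290 genes lay over 1 log2 unit outside the others, and 177 with the trend removed, against at most 13 in any other atrial library. With the trend removed log2 Nppa was 14.47 against 13.70 to 13.98. No biological explanation was tested, since the labels name none for a single animal.

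Other libraries lay far from the 3 others of their group. Chance does so in about 1 in 20 groups, and 29 of 309 gene and group pairs and 3 of 48 pairs of library measures and groups did. Groups with 3 or 4 libraries at 0 are not counted, since there any value above 0 stands apart, as for Rln3 (0.122) in control female 1 of day 12, Lypd6b (0.0207) in control female 2 of day 12, Bmp10 (0.0119) in transgenic female 1 and Nptx1 (0.00987) in control female 1 of the day 0 ventricles. Control female 1 of day 12 stood apart in Myl3 (2555 FPKM), Tnnc1 (1527), Ryr2 (20.6), Eno3 (820), Ckm (847), Phlda3 (8.86) and Kcnj3 (6.75), control male 1 in Postn (4.23) and Aldh18a1 (2.14), and control female 2 in Bhlhe41 (1.95). The deviation of control female 1 had a rank correlation of -0.55 with transcript length, so its genes need not be separate chance events. Whether that trend accounts for them was not tested. Transgenic male 1 of day 12 had a mean correlation of 0.987 and stood apart in Col8a1 (10.2), Car9 (42.7), Col1a1 (32.8), Meg3 (18.9), Ciart (1.00) and Gt(ROSA)26Sor (0.333), female 1 in Eno3 (2892) and female 2 in its estimated 17.9 M fragments. On day 3 female 2 had Rln3 at 995 and Fhl1 at 249. Before tamoxifen transgenic ventricles had female 1 apart in Gja1 (33.5), and male 1 in Pdk4 (64.1), Ptgds (149) and Wnk2 (5.93), and control ventricles male 2 in Rln3 (0.249). In atria control male 2 had Myl7 at 3128 and transgenic male 2 Myl2 at 25.1.

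By a test of the difference itself, 3508 genes changed differently from day 0 to day 12 in transgenic and control ventricles, Rln3 differed in its genotype effect between chambers (-4.57, log2), and Ackr3 between sexes (-1.04, log2), a call lost without transgenic female 1 (adjusted p = 0.061) or control male 1 (0.078).

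Other splits of the same libraries were refitted, and their calls were set beside those of the real split. A split that mixes the groups turns a real difference into spread, which lowers its count, so it is no reference without change. These counts therefore do not exclude chance, and with 35 splits the smallest share possible is 1 of 35. The real split gave the most calls for transgenic against control ventricles on day 12 (5123, with at most 99 in the other 34 of 35 splits). It also did for days 3, 6 and 12 against day 0 (3708, 4102 and 4826 against at most 1, 2 and 0). The same held for day 6 against day 3 (272 against 2), day 12 against day 6 (1355 against 1), genotype before tamoxifen in ventricles (17 against 1), isoforms (4173 against 2) and their usage (172 against 39). Of 100 splits, 1, the real, was as large for the difference in change between genotypes (3508 against 2169) and for the chambers (8327 against 1). For genotype in atria 3 of 35 splits were at least as large (3 calls in the real one, up to 13 in others). For control ventricles of day 12 against day 0 the splits decide nothing, since with 0 calls all 35 are at least as large (up to 2 calls in the others). For the genotype difference between chambers 5 of 100 splits were as large, against 1 call in the real one, and the largest had 6664. That split had 7 of the 8 atrial libraries on the same side of the contrast, so it holds the difference between chambers, a structure of the samples, and is no reference without change.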

How the results depend on the processing

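Of the alternatives, the trend on transcript length and the KEGG groups were chosen only after the result was seen, and all others were planned. Of 161 results for single named genes, 145 kept their direction and side of the threshold in every setting, 12 were lost in at least 1, 4 passed only in another setting and 0 reversed. The 4 were Nr4a1 on day 12 (adjusted p = 0.032 with only the groups compared, 0.032 with library weights and 0.043 without transgenic male 1), Nr4a2 from day 6 to 12 (0.029 with FPKM as deposited, 0.0066 with only the groups compared), its difference between chambers (0.048 with library weights) and Eno3 on day 0 (0.022 with library weights). On simulated values with 200 genes changed, far fewer than were called, limma recovered 84% of 1.5-fold and 96% of 2-fold changes for genotype on day 12. A limit from low FPKM was not tested.

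With a minimum of 5 FPKM, fewer genes were tested and 3055 differed between genotypes on day 12, 2314, 2495 and 2899 between days 3, 6 and 12 and day 0, 4517 between chambers, and 85 genes passed in isoform usage. Without a filter 6 genes passed for genotype in atria, 4 for its difference between chambers, 14 for sex and 2447 in isoform usage. With FPKM as deposited 2582 genes differed between days 6 and 12 and 2 between days in controls, and lists turned: clock genes on day 12 between genotypes (3, 1 up), matrix genes on day 6 against day 0 (5, 2 up) and glycolysis from day 6 to 12 (11, 6 up). With quantile normalization 1 gene differed in controls and 13 in atria, and lists turned: mitochondrially encoded genes on day 12 (5, 2 up), respiratory chain on day 3 (23, 11 up) and glycolysis from day 6 to 12 (5, 3 up). Library weights gave 672 genes for day 6 against 3, 2488 for day 12 against 6, 7 in controls, 45 in atria and 4 for the difference between chambers. With only the groups compared, day 6 against 3 gave 126, genotype in ventricles on day 0 gave 10 and sex gave 3. A pseudocount of 1 gave 9 in ventricles on day 0 and 15 in atria. Without the sex covariate clock genes turned (3, 1 up). Camera with an estimated correlation called 5 lists. Apart from fewer genes in the filters, the cause was not tested.

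Leaving out each library gave 4641 to 4937 genes for genotype on day 12, 3198 to 3414, 3578 to 3733 and 4297 to 4557 for days 3, 6 and 12 against day 0, 108 to 339 for day 6 against 3, 803 to 1081 for day 12 against 6, 0 to 8 in controls, 3124 to 3567 for the difference in change, 14 to 22 in ventricles and 1 to 6 in atria on day 0, 7986 to 9330 between chambers, 1 to 2 for the genotype difference between them, 0 to 226 for sex, 3600 to 3949 isoforms, 136 to 184 usage genes and 967 to 1009 named genes. Without control female 1 the clock list turned (3, 1 up).

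The replicate names did not pair the samples throughout: 32 of 108 correlations of same-named libraries were over 0.1 (-0.31 to 0.29). Of these 108, which count some pairs of libraries repeatedly, 38 were best with their own name among 4 candidates. For day 6 against day 0 and against day 3, all 4 were best with their own name, at 0.052 to 0.15 and 0.072 to 0.14. With deviations taken from group and sex means, 2 and 0 of the 4 were. With the replicate block 5052 genes passed for genotype on day 12, 3628, 4042 and 4750 for days 3, 6 and 12 against day 0, 241 and 1229 for the later steps, 0 in controls, 3434 for the difference in change, 18 in ventricles and 1 in atria on day 0, 8204 between chambers and 1 for the genotype difference between them. The block gave 4076 isoforms, 165 usage genes, 140 list calls and 990 named genes, and the clock list turned (3, 1 up). With the length trend removed 5128 genes passed for genotype on day 12, 1018 for day 12 against 6 and 4740 for day 12 against day 0.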

Other observations

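KEGG terms of the deposited gene table, as groups chosen only after the result was seen, described further genes of day 12. Against controls, 101 of 130 ribosome genes fell and 1 rose (camera adjusted p = 4.6e-11 with the preset correlation, 0.81 with an estimated correlation), and 23 of 43 proteasome genes fell and 0 rose (adjusted p = 0.81 with an estimated correlation). Without control female 1, 71 of the ribosome genes fell and 2 rose (median -0.20). Oxidative phosphorylation had 75 of 120 lower and 11 higher, valine, leucine and isoleucine degradation 23 of 43 lower and 4 higher, and cardiac muscle contraction 32 of 58 lower and 8 higher. The term on protein digestion, whose genes here are mostly collagens, had 22 of 35 higher and 3 lower. Over 286 terms and 4257 genes, Fisher's exact test called 12 terms for genes that rose and 13 for genes that fell, camera 14 with the preset correlation and 0 with an estimated one. From day 6 to day 12, 89 of 120 oxidative phosphorylation and 37 of 130 ribosome genes fell (adjusted p = 0.40 for both with an estimated correlation), and with the trend on transcript length removed 23 of the ribosome genes fell.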
